A study of Homo sapiens with 20 samples.

How the data were processed

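Total RNA from THP1 cells, a human monocytic leukaemia line made macrophage-like with phorbol ester (PMA, 200 nM for 72 h), was sequenced in 20 libraries, 4 in each of 5 groups. Libraries were stranded and read as single ends of 75 bp. Per the submitters' processing notes, reads were trimmed with Trimmomatic and aligned with STAR to hg38 (versions not stated), and featureCounts 1.5.0-p1 counted them per gene. Neither the annotation release nor the strand setting is stated, so levels of genes that overlap others or sit inside them are uncertain. The deposited values are counts per gene from the authors, with no normalization, one set per library, over 58174 gene rows in the same order in all 20 libraries. Symbols and positions (GRCh38) came from GENCODE 29, which held 57836 of the gene identifiers.

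In 18 libraries every gene count is an even number, and only GYY 1 and GYY 2 hold odd and even counts. The reason is not stated. Depth was 5035366 to 11409398 gene counts per library as deposited; where each read was counted more than once, the reads behind them are fewer. All tests used the counts as deposited, and divided counts were an alternative. Libraries of a group were checked for copies: the chi-square per degree of freedom was 1.394 to 9.891 over 30 pairs within groups, so none of these pairs is a copy, while pairs across groups were not compared in this way. Intervals, floors and depth cover counting error only, since reads without molecular identifiers are not independent molecules.

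Groups followed the sample titles: control, GYY, LPS, GYY+LPS and LPS+GYY, the order in the name being that of the labels. The treatment protocol in the labels describes another line, SH-SY5Y, with a first agent for 120 min, then the second, then 6 or 24 h. It is not stated for THP1, and neither are doses. The labels do not say that replicate numbers pair libraries, so no block was used in the main comparisons. The labels do not say that replicates were separate cultures: p-values measure only the spread between these libraries, which may be technical.

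Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr kept 17358 genes, TMM factors ran from 0.925 to 1.082, and 1 quasi-likelihood fit of all 20 libraries gave every contrast. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. Levels are CPM (counts scaled to a common library total with TMM factors), as mean ± SD with n = 4; log2 fold changes carry a standard error (SE). The comparisons were LPS with control, GYY with control, GYY+LPS with LPS, LPS+GYY with LPS, GYY+LPS with LPS+GYY, and the interaction of the 2 agents in each order. Comparing GYY+LPS with control was added after the data were seen. On simulated data with known changes, the test called 55.2% of genes changed 1.5-fold, 92.5% of those changed 2-fold and 100% of those changed 4-fold, with 5 false calls among 14412 genes. Only genes above 5 CPM were changed, and the simulated libraries shared no structure, so these rates may not hold for the real libraries.

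Before the data were examined, 26 gene lists were fixed: proinflammatory cytokines, chemokines, NF-kB pathway and feedback genes, interferon-stimulated genes, anti-inflammatory regulators, inflammasome genes, matrix remodelling genes, NRF2 targets, ATF4 amino acid response genes, ER chaperones, heat shock genes, H2S and thiol sulphur metabolism genes, metallothionein and zinc genes, cholesterol synthesis genes, hypoxia and glycolysis genes, nuclear oxidative phosphorylation genes, mitochondrial DNA encoded genes, cell cycle genes, p53 targets, lysosome genes, ribosomal protein genes, and markers of macrophages, undifferentiated myeloid cells, neuroblastoma, lymphoid cells, and epithelium and fibroblasts. A further 2 lists, early primary response genes and later genes not driven by interferon, were added after the data were seen. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast (the 2 added lists over themselves); an estimated correlation and fry stand beside it. Neuroblastoma and epithelial lists had too few tested genes for a test.

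The named genes were fixed by rule before the data were examined: per comparison the 6 largest rises and falls among called genes with at least 5 CPM in the higher group, a known symbol and no overlap between the groups' libraries, up to 4 members of each list with the smallest adjusted p, and 15 genes followed in every comparison (TNF, IL1B, IL6, CXCL8, CCL2, IL10, PTGS2, HMOX1, NQO1, GCLM, SLC7A11, NFKBIA, CTH, CBS, SQOR). A few genes that the rule names are not reported here. Genes outside the rule are marked as chosen after their values were seen. For genes with 3 counts or fewer in a group, levels are given and no fold, except 1 ratio of IFNB1 that has a 95% counting interval (exact binomial, even counts divided by 2).

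Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, RLE size factors, no filter and a stricter filter, only the groups compared, a replicate block, a fold threshold and leaving out each library. Added after the data were seen were divided counts, the share of reads assigned to genes as a covariate, protein-coding genes only, and leaving out 3 sets of libraries. The share of assigned reads was compared with a 2-sided exact permutation test.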

Results

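Gene expression was measured by RNA sequencing in macrophage-like THP1 cells. Cells were left untreated (control) or exposed to GYY4137 (GYY), a slow donor of hydrogen sulphide, or to lipopolysaccharide (LPS), a bacterial cell wall component sensed by TLR4. Further cells had both agents, in either label order. Each of the 5 groups had 4 libraries. Gene counts per library ran from 6687892 to 11156912 in control, 5035366 to 10393362 in GYY and 6561726 to 8256914 in LPS. They ran from 6436928 to 11409398 in GYY+LPS and from 6620766 to 7820188 in LPS+GYY. The share of reads assigned to genes was 26.0 ± 3.99% in control (mean ± SD, n = 4), 33.4 ± 2.95% in GYY, 24.6 ± 0.403% in LPS, 28.2 ± 4.6% in GYY+LPS and 24.5 ± 1.4% in LPS+GYY. The time between LPS and harvest is not given for these cells, so it is not known whether it was equal across groups.

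**Figure D1:**
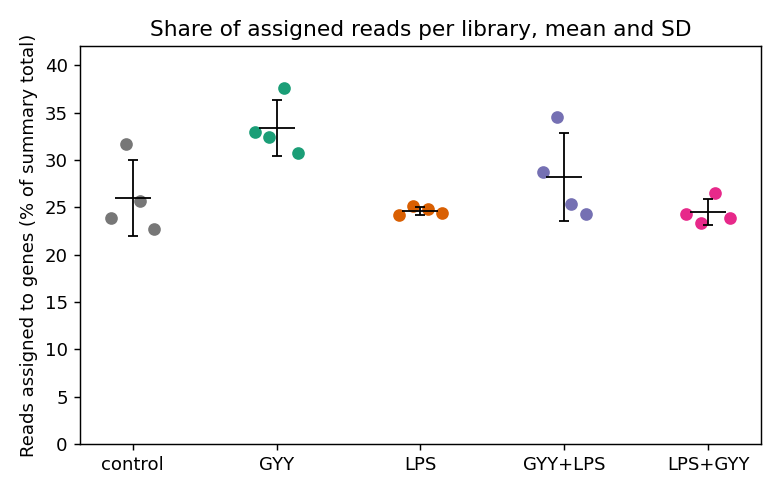
Share of reads assigned to genes (percent, vertical axis) in each library (dots) of the 5 groups, with mean and SD (bars). The 4 LPS libraries lie between 24.2% and 25.1%, while the GYY libraries reach 37.6%.

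LPS against control addressed the response to LPS alone. Interferon-stimulated genes and chemokines rose furthest. CXCL10, a chemokine that attracts T cells (ENSG00000169245, chromosome 4, 76021117 to 76023497), went from 0.348 ± 0.27 to 266 ± 40.8 CPM, a log2 fold change of 9.61 ± 0.29 (SE; adjusted p = 2.13e-20). CCL8, a chemokine for monocytes, rose by 6.58 ± 0.2 on the log2 scale (adjusted p = 3.2e-20), and IFIT2, an interferon-induced inhibitor of viral translation, by 6.56 ± 0.16 (adjusted p = 1.46e-22). IFNB1, which encodes interferon beta (ENSG00000171855, chromosome 9, 21077105 to 21077963), was at 13.5 ± 1.23 CPM with LPS and 0.0508 ± 0.102 in control, where no library held more than 2 counts. IFNL1, an interferon lambda, was at 6.98 ± 1.8 CPM with LPS and listed at 0 in control. Likewise GBP5, a guanylate-binding protein, was at 7.55 ± 1.91 CPM with LPS and 0.0694 ± 0.139 in control.

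Of 44 interferon-stimulated genes tested with LPS, 43 rose (43 adjusted over the list alone, median log2 fold change 3.71, adjusted p = 2.79e-09 with an estimated correlation). Among them were IFIT3 (5.81 ± 0.14) and the viral RNA sensor IFIH1 (2.96 ± 0.09). Of 22 chemokines 14 rose (18 adjusted over the list alone, adjusted p = 3.75e-07 with an estimated correlation). They included the macrophage chemokines CCL3 (1.28 ± 0.06) and CCL4 (1.66 ± 0.09). Of 22 proinflammatory cytokines 15 rose (16 adjusted over the list alone, adjusted p = 0.00349 with an estimated correlation). TNF, a central inflammatory cytokine, rose by 1.09 ± 0.1 (adjusted p = 2.01e-09), and IL1B, the precursor of interleukin 1 beta, by 0.77 ± 0.09 (adjusted p = 4.53e-07). IL6 rose by 2.06 ± 0.38 (adjusted p = 0.000382). NF-kB pathway and feedback genes rose in 22 of 28 cases, with 1 lower (22 and 1 adjusted over the list alone, adjusted p = 0.00157 with an estimated correlation). SOD2, a mitochondrial superoxide dismutase, rose by 0.98 ± 0.08 and the NF-kB inhibitor NFKBIA by 0.8 ± 0.07. CXCL8, a neutrophil chemokine, rose by 0.81 ± 0.08 and PTGS2, the inducible cyclooxygenase, by 1.85 ± 0.19.

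Among anti-inflammatory regulators 12 of 20 rose with LPS and 1 fell (12 and 1 adjusted over the list alone, adjusted p = 0.0029 with an estimated correlation). Its largest named rises were in SOCS3, an inhibitor of cytokine signalling (3.16 ± 0.23), and IDO1, a tryptophan-degrading enzyme (3.31 ± 0.34). Inflammasome genes rose in 9 of 13 cases (10 adjusted over the list alone, adjusted p = 0.000264 with an estimated correlation). The DNA sensor AIM2 rose by 2.84 ± 0.19. Of 29 cell cycle genes 9 fell with LPS (15 adjusted over the list alone, median -0.53, preset-correlation adjusted p = 2.38e-06, but adjusted p = 0.375 with an estimated correlation). These included the anaphase activator CDC20 (-0.69 ± 0.14) and the helicase subunit MCM7 (-0.59 ± 0.12). The largest falls were in TRAC, a T cell receptor segment (-2.0 ± 0.35), ZFP36L1, an RNA decay factor (-1.55 ± 0.21), and the homeobox gene DLX3 (-1.44 ± 0.16). The cystine transporter gene SLC7A11 (0.46 ± 0.13, adjusted p = 0.0236) and SQOR, which encodes the sulphide-oxidising enzyme of mitochondria (0.46 ± 0.08, adjusted p = 0.000127), also rose.

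The remaining lists did not pass with LPS under an estimated correlation. Members higher and lower over all genes, of those tested, were 3 and 2 of 21 for matrix remodelling, 1 and 2 of 32 for ATF4 response, 1 and 2 of 28 for hypoxia and glycolysis, 4 and 0 of 18 for p53 targets (adjusted p = 0.403 with an estimated correlation), and 4 and 1 of 30 for lysosome genes (median -0.02, mean 0.04). Adjusted over the list alone these counts were 5 and 2, 2 and 4, 3 and 2, 5 and 1, and 5 and 2. Mitochondrial DNA encoded genes (median 0.25) and ribosomal protein genes (median 0.11) passed with the preset correlation, at adjusted p = 0.00564 and 0.00149, but both had adjusted p = 0.729 with an estimated correlation. In all, 1302 of 17358 genes were called, 868 higher and 434 lower, with 361 rises and 48 falls of at least 2-fold. Leaving out the libraries numbered 4 of control, GYY and GYY+LPS, which stood apart from their groups, raised the count to 2140.

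**Figure D2:**
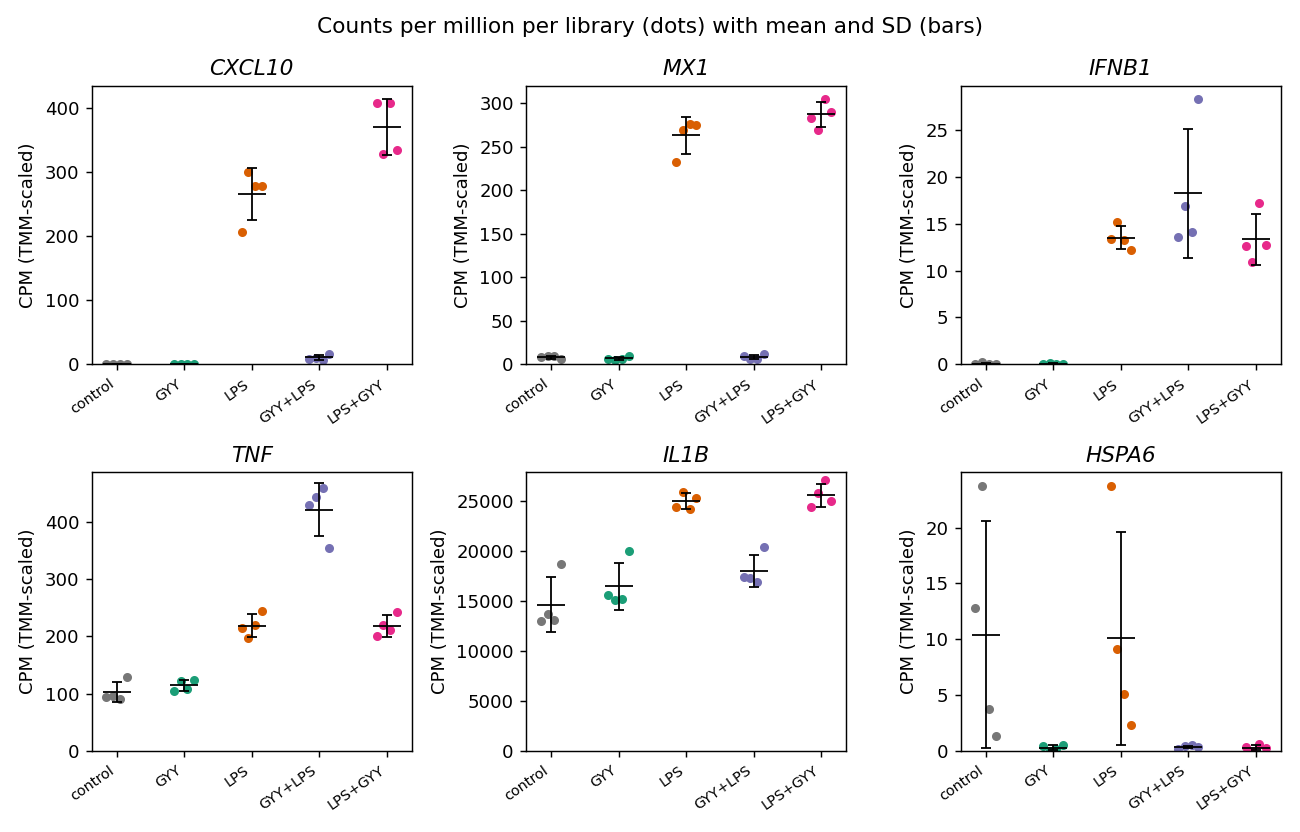
CPM (vertical axes) of CXCL10, MX1, IFNB1, TNF, IL1B and HSPA6 in each library (dots) of the 5 groups, with mean and SD (bars). MX1 is at 263 ± 21 CPM in LPS and 8.25 ± 2.48 in GYY+LPS, while IFNB1 is at 13.5 ± 1.23 and 18.2 ± 6.87.

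GYY against control addressed the response to the sulphide donor alone, and the share of assigned reads differed between these groups by 7.4 points (exact permutation p = 0.0571, adjusted p = 0.228 over 4 comparisons). HSPA6, a stress-inducible heat shock protein (ENSG00000173110, chromosome 1, 161524540 to 161526910), fell from 10.4 ± 10.2 to 0.265 ± 0.211 CPM (log2 fold change -5.2 ± 0.87, adjusted p = 0.000582). QPCTL, a glutaminyl cyclase (1.82 ± 0.36, adjusted p = 0.00212), and TLE4, a transcriptional co-repressor (1.0 ± 0.15, adjusted p = 0.000203), rose. So did TUBA1C, an alpha tubulin (0.89 ± 0.15, adjusted p = 0.000578), and CDO1, which oxidises cysteine (0.88 ± 0.22, adjusted p = 0.0102). HAVCR1, a phosphatidylserine receptor, fell (-1.89 ± 0.35). TNF (0.16 ± 0.1, adjusted p = 0.313) and IL1B (0.17 ± 0.09, adjusted p = 0.226) were not called, while CXCL8 (0.39 ± 0.08, adjusted p = 0.00287) and NFKBIA (0.35 ± 0.07, adjusted p = 0.00211) rose.

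Called genes of nuclear and mitochondrial oxidative phosphorylation went opposite ways with GYY, but neither list passed with an estimated correlation. The mitochondrial share of counts was 3.52 ± 0.559% in GYY and 5.01 ± 0.603% in control. GYY 2 and control 2, with 32.4% and 31.7% of reads assigned, had 3.1% and 4.58%, while GYY 3 and control 4, with 37.6% and 22.7% assigned, had 3.13% and 5.9%. However, GYY 4, with 30.7% assigned, had 4.3%, near control 2, and GYY 1, with 32.9% assigned, had 3.54%. Of 50 nuclear oxidative phosphorylation genes 27 rose and 1 fell (35 and 1 adjusted over the list alone, median 0.23, preset-correlation adjusted p = 8.52e-17, but adjusted p = 0.132 with an estimated correlation). COX6C (0.63 ± 0.09) and COX7A2 (0.38 ± 0.07) of cytochrome oxidase and ATP5MC3 (0.38 ± 0.07) of the ATP synthase were among them. Of 13 genes encoded by mitochondrial DNA 12 fell (12 adjusted over the list alone, median -0.49, adjusted p = 4.08e-14, but adjusted p = 0.132 with an estimated correlation). MT-ND2 of complex I fell by 0.72 ± 0.1 and MT-CYB of complex III fell by 0.57 ± 0.09. Ribosomal protein genes rose in 20 of 48 cases (25 adjusted over the list alone, adjusted p = 3.64e-13, but adjusted p = 0.5 with an estimated correlation). Of 17 sulphur metabolism genes 4 rose and 1 fell (5 and 1 adjusted over the list alone, adjusted p = 0.0248, but adjusted p = 0.132 with an estimated correlation). SQOR (0.43 ± 0.08) and AHCY, the hydrolase of S-adenosylhomocysteine (0.29 ± 0.07), rose and the methionine adenosyltransferase MAT2A (-0.49 ± 0.12) fell.

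Cholesterol synthesis genes rose in 5 of 23 cases with GYY (10 higher and 1 lower adjusted over the list alone, adjusted p = 0.00585, but adjusted p = 0.132 with an estimated correlation). Squalene epoxidase, SQLE, rose by 0.3 ± 0.07. Of 21 ER chaperone genes 5 rose and 1 fell, and 8 and 2 adjusted over the list alone (adjusted p = 0.000394, but adjusted p = 0.531 with an estimated correlation). Of 26 NRF2 targets 4 rose and 1 fell, and 4 and 1 adjusted over the list alone (adjusted p = 0.0396, but adjusted p = 0.531 with an estimated correlation). Of 9 metallothionein and zinc genes 2 rose, and 2 adjusted over the list alone (adjusted p = 0.00268, but adjusted p = 0.531 with an estimated correlation). Thioredoxin TXN (0.44 ± 0.07) and the ferritin chain FTH1 (0.35 ± 0.08) rose. The NRF2 targets HMOX1 (-0.16 ± 0.1, adjusted p = 0.311), NQO1 (0.09 ± 0.17, adjusted p = 0.785) and GCLM (-0.19 ± 0.14, adjusted p = 0.384) were not called. Heat shock genes rose in 7 and fell in 2 of 21 cases (8 and 3 adjusted over the list alone, adjusted p = 0.0771), with a median of 0.11 and a mean of -0.26. The mitochondrial chaperone HSPD1 (0.37 ± 0.07) and HSP90AA1 (0.35 ± 0.07) rose, while HSPA1A (-1.4 ± 0.33), whose reads cannot be told from those of its near copy, fell.

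With GYY, 2116 genes were called, 972 higher and 1144 lower, of which 9 and 467 changed at least 2-fold. Which direction held more calls depended on the tool. DESeq2 called 1293 higher and 1141 lower, limma-voom 1052 and 869, and edgeR with RLE size factors 1101 and 1100. Genes not annotated as protein-coding, those without a known type included, made up 59.9% of the falls, 3.9% of the rises and 30.2% of the genes tested. With the share of assigned reads as a covariate 64 genes were called, 52 of them among the 2116. TLE4 (0.79, adjusted p = 0.0443) and HSPA6 were among the 64 but not QPCTL, TUBA1C, CXCL8, NFKBIA or SQOR. Under that covariate the log2 fold changes of QPCTL, TUBA1C, CXCL8, NFKBIA and SQOR were 1.36, 0.54, 0.36, 0.32 and 0.34 (adjusted p = 0.128, 0.123, 0.0678, 0.0746 and 0.0849). Without GYY 3 the count was 638, without control 1 it was 1118 and without control 4 it was 1211. Without GYY 1 and 2, the libraries with odd counts, it was 934. HSPA6 was not called with limma-voom (adjusted p = 0.123; range over its alternatives 3.12e-31 to 0.123), and its near copy HSPA7 shares reads with it.

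GYY+LPS against LPS addressed what GYY named first changed in LPS-treated cells. Interferon-stimulated transcripts were far lower. MX1, an interferon-induced antiviral GTPase (ENSG00000157601, chromosome 21, 41420304 to 41459214), was at 8.25 ± 2.48 CPM in GYY+LPS, 263 ± 21 in LPS and 8.06 ± 1.61 in control. Its log2 fold change was -5.02 ± 0.15 (adjusted p = 1.46e-19). CXCL10 (-4.71 ± 0.18, adjusted p = 1.13e-17), CCL8 (-4.95 ± 0.17, adjusted p = 1.7e-18) and the antiviral genes CMPK2 (-5.51 ± 0.26) and RSAD2 (-5.23 ± 0.26) fell too. TNFSF10, the death ligand TRAIL, was at 0.0912 ± 0.105 CPM against 15.3 ± 2.06 in LPS. TNF went the other way, from 219 ± 19.5 to 422 ± 46 CPM (0.95 ± 0.1, adjusted p = 3.38e-08). IFNB1, named here after its values were seen, was at 18.2 ± 6.87 CPM against 13.5 ± 1.23.

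Of 44 interferon-stimulated genes 43 fell in GYY+LPS (43 adjusted over the list alone, median -2.76, adjusted p = 4.86e-09 with an estimated correlation). The antiviral GTPase MX2 (-3.61 ± 0.12) and PARP9 (-3.02 ± 0.1) were among them. Chemokines fell in 14 of 22 cases (16 adjusted over the list alone, median -0.56, adjusted p = 6.62e-05 with an estimated correlation), CCL3 (-0.52 ± 0.06) included. Inflammasome genes fell in 5 of 13 cases (8 adjusted over the list alone, adjusted p = 0.00054 with an estimated correlation). AIM2 was at -3.1 ± 0.19 and the membrane rupture gene NINJ1 at -0.53 ± 0.11. Anti-inflammatory regulators fell in 10 of 20 cases (11 lower and 1 higher adjusted over the list alone, adjusted p = 0.0218 with an estimated correlation). SOCS3 was at -2.32 ± 0.22 and IDO1 at -2.73 ± 0.33. Of 22 cytokines 11 fell and 1 rose, and 13 and 1 adjusted over the list alone (adjusted p = 3.28e-07, but adjusted p = 0.145 with an estimated correlation). Of 28 NF-kB genes 12 fell and 1 rose, and 14 and 4 adjusted over the list alone (adjusted p = 0.0006, but adjusted p = 0.321 with an estimated correlation). IL1B (-0.47 ± 0.09), CXCL8 (-0.37 ± 0.08), PTGS2 (-0.99 ± 0.18) and GCLM, a subunit of the glutathione synthesis enzyme (-0.51 ± 0.13, adjusted p = 0.0177), fell. IL6 (-1.12 ± 0.36, adjusted p = 0.057), NFKBIA (0.11 ± 0.07, adjusted p = 0.383) and SQOR (-0.22 ± 0.08, adjusted p = 0.0862) were not called.

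Of 29 cell cycle genes 7 were higher in GYY+LPS than in LPS (14 adjusted over the list alone, median 0.49, adjusted p = 3.28e-07, but adjusted p = 0.321 with an estimated correlation). MCM7 was at 0.61 ± 0.12 and the transcription factor E2F1 at 0.89 ± 0.23. Of 21 ER chaperone genes 7 were higher and 1 lower, and 11 and 1 adjusted over the list alone (median 0.3, adjusted p = 0.00108, but adjusted p = 0.648 with an estimated correlation), with calreticulin, CALR, at 0.48 ± 0.09. Of 13 mitochondrial DNA encoded genes 2 were lower, and 9 adjusted over the list alone (median -0.25, adjusted p = 0.00108, but adjusted p = 0.648 with an estimated correlation). Of 32 ATF4 response genes 6 were higher and 1 lower, and 8 and 1 adjusted over the list alone (adjusted p = 0.042, but adjusted p = 0.515 with an estimated correlation). The serine synthesis enzymes PSAT1 (0.84 ± 0.17) and PHGDH (0.69 ± 0.14) were higher. Of 50 nuclear oxidative phosphorylation genes 4 were higher, and 5 adjusted over the list alone (adjusted p = 0.00713, but adjusted p = 0.653 with an estimated correlation). The largest rises included the organic anion transporter SLCO2B1 (1.41 ± 0.31), the cell surface proteoglycan GPC4 (1.08 ± 0.21) and the adrenergic receptor ADRA2B (1.02 ± 0.21). HSPA6 was again lower (-4.88 ± 0.81, adjusted p = 0.000147, but adjusted p = 0.104 with limma-voom).

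In GYY+LPS against LPS 1091 genes were called, 408 higher and 683 lower, 30 and 315 of them by at least 2-fold. With the share of assigned reads as a covariate 827 were called, 215 higher and 612 lower, and 704 of them were among the 1091. The count was 607 without GYY+LPS 1, 652 without GYY+LPS 2, 703 without LPS 2, 684 without LPS 3, 1924 without GYY+LPS 4, and 2570 without the 3 libraries numbered 4. The call of GCLM was lost without GYY+LPS 3, LPS 2 or LPS 4 (highest adjusted p = 0.0722).

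**Figure D3:**
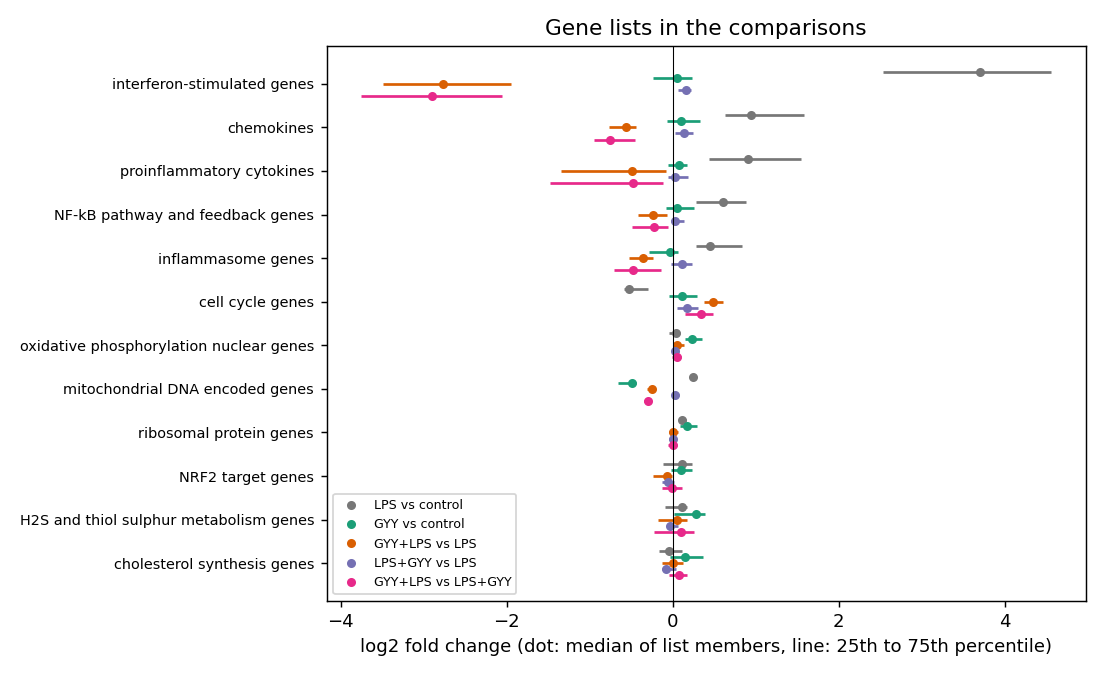
Median log2 fold change of list members (dots) with the 25th to 75th percentile (lines) for 12 gene lists in 5 comparisons. Interferon-stimulated genes have medians of 3.71 in LPS against control, -2.76 in GYY+LPS against LPS and 0.16 in LPS+GYY against LPS.

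LPS+GYY against LPS addressed what GYY named second changed, and few genes were called in the fit of all 20 libraries. LIF, a cytokine of the interleukin 6 family, fell from 152 ± 8.48 to 103 ± 4.09 CPM (-0.57 ± 0.08, adjusted p = 0.000918), and HSPA6 fell by 5.07 ± 0.88 (adjusted p = 0.00951). AGER, a receptor for glycated proteins (0.93 ± 0.17, adjusted p = 0.0142), SEMA6B, a semaphorin (1.23 ± 0.24, adjusted p = 0.0231), and TNFAIP8L3, a phosphoinositide transfer protein (0.78 ± 0.13, adjusted p = 0.00583), rose. So did TUBA1C (0.79 ± 0.16, adjusted p = 0.0231) and the metalloproteinase inhibitor TIMP3 (0.58 ± 0.09, adjusted p = 0.00514). TNF (-0.01 ± 0.1, adjusted p = 0.997), IL1B (0.04 ± 0.09, adjusted p = 0.958) and CXCL10 (0.48 ± 0.14, adjusted p = 0.221) were not called. Of 44 interferon-stimulated genes edgeR called 0, and 0 adjusted over the list alone, with 9 at an unadjusted p under 0.05, while DESeq2 and limma-voom each called 0. Their median of 0.16 passed with the preset correlation (adjusted p = 2.61e-05, but adjusted p = 0.572 with an estimated correlation). Of 21 matrix remodelling genes 1 was higher, and 4 adjusted over the list alone (adjusted p = 0.0154, but adjusted p = 0.297 with an estimated correlation). Of 21 macrophage markers edgeR, DESeq2 and limma-voom each called 0, and 0 adjusted over the list alone, with 6 at an unadjusted p under 0.05 (median 0.15, adjusted p = 0.0221, but adjusted p = 0.297 with an estimated correlation). Of 29 cell cycle genes the 3 tools each called 0, with 4 at an unadjusted p under 0.05 and 3 adjusted over the list alone (adjusted p = 0.00471, but adjusted p = 0.641 with an estimated correlation).

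In LPS+GYY against LPS edgeR called 25 genes, 20 higher and 5 lower, with 1569 at an unadjusted p under 0.05. DESeq2 called 110, the fit of only these groups 328, and the share covariate 149. Pairs of libraries within LPS and within LPS+GYY had a chi-square per degree of freedom of at most 2.086, against up to 9.891 within control. The fit of all 20 libraries shares the estimate of the spread, so the count of 25 depends on libraries of the other groups. The count was 9 without LPS+GYY 1, 7 without LPS+GYY 3, 4 without LPS 1, 7 without LPS 2 and 3 without LPS 3. HSPA6 lost its call with limma-voom (adjusted p = 0.481), without LPS+GYY 1 and without LPS 1. TUBA1C lost it in 8 of 21 alternatives (highest adjusted p = 0.127), SEMA6B in 5 (0.159) and AGER in 4 (0.0797).

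GYY+LPS against LPS+GYY addressed whether label order mattered. MX1 (-5.14 ± 0.15, adjusted p = 7.99e-20), CXCL10 (-5.19 ± 0.19, adjusted p = 2.05e-18) and CCL8 (-5.05 ± 0.17, adjusted p = 1.06e-18) were lower in GYY+LPS than in LPS+GYY. TNF was higher by 0.95 ± 0.1 (adjusted p = 2.76e-08). IL6 (-1.51 ± 0.35, adjusted p = 0.00659), PTGS2 (-1.2 ± 0.18), IL1B (-0.51 ± 0.09), CXCL8 (-0.44 ± 0.08), SLC7A11 (-0.63 ± 0.13) and the monocyte chemokine CCL2 (-0.9 ± 0.25, adjusted p = 0.0257) were lower. Of 17 sulphur metabolism genes only 2 were called, both lower. They were SQOR (-0.3 ± 0.08, adjusted p = 0.0164) and CTH, which makes hydrogen sulphide from cysteine (-0.95 ± 0.29, adjusted p = 0.0393). AZU1, a granule protein of myeloid precursors, was higher (1.16 ± 0.26, adjusted p = 0.00502), as was ITPKB, an inositol phosphate kinase (1.1 ± 0.25, adjusted p = 0.00423).

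By label order, 43 of 44 interferon-stimulated genes were lower in GYY+LPS (43 adjusted over the list alone, median -2.9, adjusted p = 4.61e-09 with an estimated correlation). So were 15 of 22 chemokines (18 adjusted over the list alone, adjusted p = 3.67e-05 with an estimated correlation) and 7 of 13 inflammasome genes (8 adjusted over the list alone, adjusted p = 0.000228 with an estimated correlation). AIM2 was at -3.08 ± 0.19 and the caspase CASP1 at -1.38 ± 0.22. The next 4 lists passed with the preset correlation and with fry, but not with an estimated correlation. Of 22 cytokines 11 were lower and 1 higher, and 14 and 2 adjusted over the list alone (adjusted p = 0.217 with an estimated correlation). Of 28 NF-kB genes 12 were lower and 1 higher, and 13 and 1 adjusted over the list alone (adjusted p = 0.246 with an estimated correlation). Of 20 anti-inflammatory regulators 9 were lower and 1 higher, and 12 and 1 adjusted over the list alone (adjusted p = 0.05 with an estimated correlation). Of 21 matrix remodelling genes 5 were lower, and 7 adjusted over the list alone (adjusted p = 0.241 with an estimated correlation). ER chaperones, heat shock genes, mitochondrial DNA encoded genes and cell cycle genes had adjusted p = 0.555, 0.478, 0.478 and 0.481 with an estimated correlation. Of the glycolysis genes, HK2, a hexokinase (-0.84 ± 0.14), and PFKFB3, an activator of glycolysis (-0.71 ± 0.1), were lower. The test called 1347 genes, 395 higher and 952 lower, 19 and 421 of them by at least 2-fold. With the share of assigned reads as a covariate 967 were called, 177 higher and 790 lower, and 847 of them were among the 1347. The count was 849 without GYY+LPS 1, 826 without GYY+LPS 2, 2179 without GYY+LPS 4 and 2739 without the 3 libraries numbered 4. CCL2 lost its call in 6 of 21 alternatives (highest adjusted p = 0.0787), SQOR in 3 (0.0889) and CTH in 11 of 20 (0.209).

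The interactions asked whether the change with GYY differed when LPS was present. In GYY+LPS 385 genes were called, 61 higher and 324 lower. CXCL10 (-5.3 ± 0.95, adjusted p = 0.000796) and BATF2, a transcription factor induced by interferon (-5.11 ± 0.35, adjusted p = 1.46e-11), were lower than the separate changes sum to. TNF was higher (0.78 ± 0.14, adjusted p = 0.000746). IL1B (-0.65 ± 0.13), CXCL8 (-0.75 ± 0.11), PTGS2 (-1.39 ± 0.26), SQOR (-0.66 ± 0.11) and SLC7A11 (-0.73 ± 0.18, adjusted p = 0.0254; highest over its alternatives 0.0724) were lower too. Of 44 interferon-stimulated genes 41 were lower (42 adjusted over the list alone, adjusted p = 3.25e-07 with an estimated correlation), and of 22 chemokines 7 (12 adjusted over the list alone, adjusted p = 0.00213 with an estimated correlation). So were 1 of 13 inflammasome genes (5 adjusted over the list alone, adjusted p = 0.00443 with an estimated correlation) and 3 of 20 anti-inflammatory regulators (6 adjusted over the list alone, adjusted p = 0.0362 with an estimated correlation). Of 22 cytokines 4 were lower and 1 higher (12 and 1 adjusted over the list alone, adjusted p = 0.14 with an estimated correlation), and of 28 NF-kB genes 7 were lower (12 lower and 4 higher adjusted over the list alone, adjusted p = 0.112 with an estimated correlation). Mitochondrial DNA encoded, nuclear oxidative phosphorylation, ribosomal protein, NRF2, metallothionein and cell cycle lists had medians of 0.26, -0.18, -0.15, -0.15, -0.64 and 0.35 in the GYY+LPS interaction. They passed with the preset correlation (adjusted p = 0.00596, 5.63e-05, 3.18e-07, 0.00414, 0.000137 and 0.00149, but adjusted p = 0.526, 0.317, 0.391, 0.239, 0.239 and 0.413 with an estimated correlation). In LPS+GYY 295 genes were called, 176 higher and 119 lower. TLE4 was lower (-1.27 ± 0.21, adjusted p = 0.0078), and TNF (-0.17 ± 0.14, adjusted p = 0.554) and IL1B (-0.14 ± 0.13, adjusted p = 0.607) were not called. With an estimated correlation no list passed in the LPS+GYY interaction. Mitochondrial DNA encoded genes were higher in 7 of 13 cases (12 adjusted over the list alone, median 0.57, adjusted p = 3.66e-12, but adjusted p = 0.208 with an estimated correlation). Of 50 nuclear oxidative phosphorylation genes 1 was lower (16 lower and 1 higher adjusted over the list alone, median -0.23, adjusted p = 1.24e-10, but adjusted p = 0.208 with an estimated correlation). Of 48 ribosomal protein genes 3 were lower (13 adjusted over the list alone, median -0.18, adjusted p = 6.43e-10, but adjusted p = 0.615 with an estimated correlation). Of 23 cholesterol synthesis genes 1 was lower (5 adjusted over the list alone, median -0.16, adjusted p = 0.0025, but adjusted p = 0.208 with an estimated correlation). NRF2, ER chaperone, heat shock, sulphur metabolism and metallothionein lists had medians of -0.18, -0.18, -0.07, -0.14 and -0.32 (preset-correlation adjusted p = 0.0147, 0.0141, 0.0369, 0.0416 and 0.0416, but adjusted p = 0.582, 0.638, 0.615, 0.208 and 0.638 with an estimated correlation). Genes not annotated as protein-coding made up 56.2% of the rises. The count of 295 fell to 29 with the share covariate and to 18 without GYY 3, and reached 1088 without control 2. In GYY+LPS the count was 590 without GYY+LPS 2 and 708 with the covariate.

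Genes called in GYY against control were followed into LPS-treated cells, where no library is shared. The 972 genes higher with GYY had a median log2 fold change of 0.13 in GYY+LPS against LPS (adjusted p = 0.0822 over 4 tests, limma fry) and 0.04 in LPS+GYY against LPS (adjusted p = 0.632). The 1144 lower genes had -0.29 (adjusted p = 0.0822) and 0 (adjusted p = 0.979). Camera at the preset correlation gave unadjusted p = 4.32e-09 for the higher and 3.45e-11 for the lower genes in GYY+LPS against LPS. In LPS+GYY against LPS it gave 0.0182 and 0.489, and an estimated correlation was not used here. The sign was the same for 80.7% and 87.2% of these genes in GYY+LPS, and for 61.4% and 49.8% in LPS+GYY. Across genes, which are not independent replicates, the fold changes with GYY correlated with those of GYY+LPS at a Pearson r of 0.308 and Spearman rho of 0.347, and with those of LPS+GYY at 0.01 and 0.02. Genes that LPS raised, with the LPS libraries split 2 against 2 so that none served both steps, had a median of -0.74 in GYY+LPS against LPS (-0.79 to -0.68 over 6 splits), 0.08 in LPS+GYY against LPS (0.06 to 0.11) and -0.63 in GYY+LPS against LPS+GYY. Genes that LPS lowered had 0.34 (0.3 to 0.4), 0.07 (0.03 to 0.09) and 0.26. GYY+LPS and LPS+GYY shared 5 higher and 2 lower calls against LPS, where independent lists would share 0.47 and 0.197. Because both use the same LPS libraries, their fold changes correlate without any effect. The correlation was 0.265, against 0.506 in simulated unchanged groups (0.496 to 0.518 over 20 simulations), and the covariance was 0.0381, against 0.0381. With separate LPS libraries the medians were 0.5 shared higher and 0.5 shared lower calls.

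Marker genes were used to look at the cell types present. Macrophage markers summed to 3029 ± 118 CPM in LPS and 3293 ± 227 in LPS+GYY, the lowest and highest group means. Of 24 such markers 21 passed the filter, but their levels were uneven. Among single markers, chosen after their values were seen, APOE averaged 908 CPM over all libraries and SPI1 344. By contrast LYZ averaged 0.125 CPM, MRC1 0.264, VSIG4 0.504, CD163 1.76 and CD68 4.4. Other genes overlap 81.7% of the CD68 exons and 34% of the LYZ exons, so both levels are uncertain, and the low LYZ value does not show that LYZ is absent. With LPS 3 of 21 were higher and 2 lower (4 and 5 adjusted over the list alone, median 0.04, adjusted p = 0.978 with an estimated correlation), CSF1R, the receptor of a macrophage growth factor, among the lower (-0.44, adjusted p = 0.00753). Undifferentiated myeloid markers summed to between 78.6 ± 4.89 CPM in LPS+GYY and 113.8 ± 27.9 in control. Of 7 tested, 2 were higher in GYY+LPS than in LPS+GYY (3 adjusted over the list alone, adjusted p = 0.0484, but adjusted p = 0.478 with an estimated correlation). Neuroblastoma markers, listed because the protocol text concerns SH-SY5Y, summed to at most 0.983 ± 0.565 CPM in any group, and epithelial and fibroblast markers to at most 3.48 ± 1.33. Lymphoid markers summed to 579 ± 259 CPM in GYY+LPS and 1027 ± 116 in LPS+GYY, nearly all from GNLY, which encodes granulysin (mean 753 CPM). With LPS 1 of 5 fell, TRAC (1 adjusted over the list alone, adjusted p = 0.729 with an estimated correlation). IL10, an anti-inflammatory cytokine, and CBS, an enzyme that can make hydrogen sulphide, had 0 counts in all 20 libraries, which allows up to 0.0348 CPM over all libraries (3 reads, the even counts divided by 2). CBS has a near-identical copy in the annotation, so its reads cannot be placed.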

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

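The tests of genomic DNA, of a GYY response in LPS-treated cells and of the GYY+LPS pattern, and the splits of GYY+LPS against control, were chosen after the results were seen; the other splits and the test of RNA composition were not.

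Other splits of the same libraries into groups of 4 were counted for each comparison. For LPS against control 1 of 35 splits, the real one, called as many genes (1302, highest other 20). That is the smallest share that 35 splits can give, and it is not adjusted over the comparisons. Splits that mix 2 different groups also widen the spread, which lowers their counts. Chance is thus argued against but not excluded. The same holds for GYY+LPS against LPS (1 of 35, real 1091, highest other 1), LPS+GYY against LPS (1 of 35, real 25, highest other 0) and GYY+LPS against LPS+GYY (1 of 35, real 1347, highest other 0). For GYY against control the real split also called the most genes (1 of 35, real 2116). But the split that set control 2 with GYY 1, 2 and 3 called 1650 genes, which points to a structure of the samples. For GYY+LPS against control 3 of 35 splits, the real one included, called at least as many (real 107, highest other 942), so chance is not excluded. A split calling that many points to a structure of the samples.

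The change with GYY differed between cells with and without LPS for 385 genes in GYY+LPS and for 295 in LPS+GYY, by a test of the interaction. In the first 35 splits drawn 2, the real one included, called as many genes in each interaction, which did not exclude chance. These draws shuffled the labels of all groups in the interaction, which also breaks up the LPS effect. They are thus no strict null for an interaction. The draws were raised to 100 after that was seen. In those 100, counting the real one, 2 splits called as many as the real 385 in GYY+LPS (highest other 480) and 4 called as many as the real 295 in LPS+GYY (highest other 1070). A number of draws raised after the first outcome was seen does not exclude chance. In LPS+GYY the other splits that called several times the real count point to a structure of the samples.

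GYY against control called 2116 genes while the share of assigned reads was 33.4% in GYY and 26.0% in control. Genomic DNA among the unassigned reads is argued against, since read density in 383 olfactory receptor genes was at most 1.92% (upper 95% limit) of an even spread of those reads. An RNA composition that goes with the share may be a cause and stays open. Its slope within the 12 LPS-treated libraries predicts 45.7% of the median change of the higher genes and 59.4% of that of the lower genes. At least 50% of both was asked for. Without GYY+LPS 2 the values were 51.3% and 59.6%, and from single groups 41.7% to 105.2% and 51.8% to 67.4%. The highest of these, 105.2% and 67.4%, came from LPS alone. Its libraries span only 24.2% to 25.1% of reads assigned, too narrow a range to fix a slope. For a response to GYY4137 that does not need LPS to be absent, the values were mixed. In LPS+GYY against LPS the higher and lower sets kept 9.9% and 0% of their median log2 fold change. Both lie under the bound of 10% that was to count against such a response, the first just so. In GYY+LPS against LPS they kept 33.8% and 33.4% (adjusted p = 0.0822 for both, limma fry). By the bound, the LPS+GYY values count against such a response, but the bound was chosen after the results were seen. It did not cover GYY+LPS, where the share of assigned reads was 3.57 points above that of LPS (exact permutation p = 0.143). The GYY+LPS values thus cannot tell a response to GYY4137 from a composition that goes with the share, and the response is left open.

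GYY+LPS libraries held IFNB1 (18.2 ± 6.87 CPM, against 13.5 ± 1.23 in LPS) while MX1 (8.25 ± 2.48), MX2 (8.0 ± 1.13), CMPK2 (2.53 ± 1.67) and RSAD2 (0.734 ± 0.355) lay near their control means of 8.06, 7.92, 2.46 and 0.81 CPM, though 12 of 44 interferon-stimulated genes were above control (20 adjusted over the list alone, adjusted p = 0.000428 with an estimated correlation), IFIT2 by 5.21, IFIT3 by 3.5 and IFIT1 by 3.24 on the log2 scale. Libraries without LPS under the GYY+LPS label are argued against, since the lowest GYY+LPS library held 67 times the IFNB1 of the highest control or GYY library (78 reads against 1, 95% counting interval 11.7 to 2680), while an exchange of the GYY+LPS and LPS+GYY labels was not tested and stays open. A change in interferon signalling alone is argued against by fry but not excluded. Of 29 later genes not driven by interferon 14 were lower than in LPS (21 adjusted over the list alone, median -0.46, adjusted p = 0.00243 with fry and 1.12e-10 with camera, but adjusted p = 0.126 with an estimated correlation). That list was drawn up after the data were seen, and indirect effects of interferon on its genes were not tested. A weaker or shorter LPS response throughout may be a cause and stays open. The same prediction, early genes lower as a set, served for both, so it cannot tell a weaker response from a shorter one. Of 31 early primary response genes 12 were lower and 2 higher (13 and 4 adjusted over the list alone, median -0.15, adjusted p = 0.00366 with fry, but adjusted p = 0.183 with an estimated correlation). TNF was higher, which a weaker response of TNF itself would not give. It does not count against a shorter response, since no time course was measured. In the interaction the early and later genes were lower at medians of -0.37 and -0.65 (7 lower and 1 higher, and 10 lower, or 14 and 3, and 15, adjusted over the list alone, adjusted p = 0.0212 for both with an estimated correlation). The share of the LPS rise kept was the log2 fold change of GYY+LPS against control, as a percentage of that of LPS against control. It is a share on the log2 scale and differs from the share of CPM kept. Members were those called higher with LPS, and the same LPS and control libraries served the call and the share, which can bias it. On this scale 23 early genes kept a median of 69.7% (quartiles 58.5% to 116.4%), 20 later genes 38.2% (31% to 46.2%) and 22 NF-kB genes 55.7% (42% to 63.4%). A median of 52.1% (37.7% to 62.1%) was kept by 14 chemokines, 22.2% (12.1% to 42.2%) by 15 cytokines and 11.7% (4.3% to 30.3%) by 43 interferon-stimulated genes. The time from LPS to harvest in each group is not stated.

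Library measures and named genes with at least 5 CPM were examined for 1 library far from the other 3 of its group, in 403 groups. Of these 47 had such a library. Chance flags about 1 in 20 groups, and genes of one library are not independent. Of the 47, 8 were in control 4, 11 in GYY 4 and 7 in GYY+LPS 4, and no explanation for that was tested. In these libraries GNLY, at 958 to 1120 CPM, was near the lymphoid marker sums of LPS (925 ± 63.6) and LPS+GYY (1027 ± 116), which are nearly all GNLY. IFIT2, which LPS raised, was instead lower in control 4. Whether a structure of the samples goes with the groups, and so enters the comparisons, cannot be told from the labels.

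In control 4, GNLY was at 1120 CPM (402 to 463 in the others), IL1B at 18700 (12900 to 13700), IL6 at 7.22 (1.11 to 1.83), SLC7A11 at 230 (156 to 164) and TNF at 128 (91 to 96.3), while IFIT2 was at 5.38 (9.44 to 9.8), ITPKB at 11.9 (25 to 27.4) and MAT2A at 40.5 (49.7 to 51). In GYY 4, GNLY was at 1100 CPM (490 to 513), IL1B at 20000 (15100 to 15600), SLC7A11 at 303 (190 to 201), PTGS2 at 140 (71.9 to 75.4), HMOX1 at 458 (346 to 352) and NFKBIA at 653 (589 to 596). There NINJ1 was at 301 (237 to 245), CMPK2 at 5.67 (1.56 to 1.63), IDO1 at 6.85 (2.73 to 3.12), LPAR6 at 20.1 (11.5 to 12.9) and PARP9 at 18.9 (14.4 to 15). In GYY+LPS 4, GNLY was at 958 CPM (429 to 459), IL1B at 20300 (16800 to 17400), NINJ1 at 411 (259 to 272), IDO1 at 12 (3.35 to 4.54) and DUSP7 at 40 (32.8 to 34), while GPC4 was at 14.5 (19.9 to 20.9) and ZFP36L1 at 16.9 (23.7 to 24.1).

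In LPS 2 the mitochondrial share of counts was 4.86% (5.58% to 5.66% in the others), MT-CYB was at 3520 CPM (4110 to 4140) and MT-ND2 at 3000 (3560 to 3590). In LPS 1, AIM2 was at 19.2 CPM (26.3 to 27.2), CCL8 at 123 (169 to 178), MX1 at 232 (269 to 276) and SEMA6B at 3.74 (5.38 to 5.56), and in LPS 4 CCL3 was at 10500 (10900 to 11000). COX7A2 was at 535 CPM in control 2 (490 to 493), 746 in GYY 3 (613 to 631) and 613 in LPS+GYY 3 (558 to 563). In LPS+GYY 3, HSP90AA1 was at 962 CPM (845 to 863), IL6 at 19.1 (15.9 to 16.4) and TNFAIP8L3 at 24.7 (27.3 to 27.7). The rest were E2F1 at 21 CPM in GYY+LPS 3 (11.4 to 11.9), MAT2A at 40 in GYY+LPS 1 (47.4 to 48.6), GCLM at 19.3 in GYY 1 (24.1 to 25) and RARA at 9.36 in GYY 3 (10.9 to 11.1). In LPS+GYY, AHCY was at 79.9 CPM in library 2 (91 to 91.9) and NQO1 at 42.6 in library 4 (34.5 to 35), and in control 3 LIF was at 75.2 (87.2 to 89).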

How the results depend on the processing

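The share covariate, divided counts, protein-coding genes only and leaving out 3 sets of libraries were tests chosen after the data were seen, as was everything on GYY+LPS against control. Of 942 results for single genes, 21521 alternatives left 19429 on the same side of the threshold, took 1202 below it and 890 past it, and reversed 0. Of 168 list results, 2400 alternatives left 2214 as they were, took 121 below and 65 past the threshold, and reversed 0. Of 252 alternatives to the counts and set medians, 170 stayed within their limits. Values beyond them follow. Where fewer genes or libraries enter, or a fold limit is added, the alternative itself lowers or changes the count, and otherwise the cause was not tested. Calls with an absolute log2 fold change of at least 1 were 409 for LPS against control, 476 for GYY against control, 345 for GYY+LPS against LPS, 3 for LPS+GYY against LPS, 440 for GYY+LPS against LPS+GYY, 201 and 101 for the interactions in GYY+LPS and LPS+GYY, and 40 for GYY+LPS against control. Without the libraries numbered 4 of control, GYY and GYY+LPS, they were 2140 for LPS against control, 2570 for GYY+LPS against LPS, 128 for LPS+GYY against LPS, 2739 for GYY+LPS against LPS+GYY, 636 and 678 for the interactions and 165 for GYY+LPS against control. With only the groups compared, counts were 1296 for GYY against control, 328 for LPS+GYY against LPS, 825 for the interaction in LPS+GYY and 60 for GYY+LPS against control. With the share covariate they were 64, 149, 29 and 177 in that order, and 708 for the interaction in GYY+LPS. Without GYY 1 and 2, GYY against control had 934 and the interaction in LPS+GYY 58. With protein-coding genes only, GYY against control had 1225. DESeq2 gave 110 for LPS+GYY against LPS, 788 for the interaction in LPS+GYY and 186 for GYY+LPS against control. No filter gave 83, 952 and 178 for these, and 649 for the interaction in GYY+LPS. Without the control, GYY and GYY+LPS libraries of highest assigned share, LPS+GYY against LPS had 65 and the interactions 675 and 866. A replicate block gave 637 for the interaction in LPS+GYY. Deviations from the group means correlated at -0.143 to 0.444 over 40 pairs of libraries with the same number, and over 0.1 in 5 of them. Among the 5 were the 3 pairs of control 4, GYY 4 and GYY+LPS 4 (0.285, 0.301 and 0.309) and control 2 with GYY+LPS 2 (0.444), a hint from the data, not the design, of structure that some numbers share. GYY 3 and GYY+LPS 2, with different numbers, were at 0.351, and 9 libraries correlated best with their own number. With an estimated correlation 17 list tests passed. Medians of genes that LPS raised by at least 1 were -1.47 in GYY+LPS against LPS, -1.48 in GYY+LPS against LPS+GYY and 0.13 in LPS+GYY against LPS, and of genes it lowered 0.55, 0.44 and 0.13. For raised genes the block gave -0.66 and unsplit LPS libraries -0.59 in GYY+LPS against LPS, and unsplit libraries gave 0.05 and 0.14 for raised and lowered genes in LPS+GYY against LPS. Shared calls with split LPS libraries had a median of 0.5 higher and 0.5 lower. Leaving out each library in turn gave 973 to 1673 for LPS against control, 638 to 2832 for GYY against control, 607 to 1924 for GYY+LPS against LPS, 3 to 23 for LPS+GYY against LPS, 826 to 2179 for GYY+LPS against LPS+GYY, 290 to 590 and 18 to 1088 for the interactions, 80 to 133 for GYY+LPS against control and 59 to 76 list tests. For the interaction in LPS+GYY the count was 160, 123, 18 and 712 without GYY 1 to 4, 68, 1088 and 183 without control 1, 2 and 4, 75, 56 and 107 without LPS+GYY 1, 2 and 4, and 101, 42, 95 and 155 without LPS 1 to 4. The call of SLC7A11 in LPS against control was lost in 6 of 21 alternatives (highest adjusted p = 0.0904). Divided counts gave 1336, 2458, 1169, 25, 1434, 407, 387 and 110 for the comparisons in the order first given. Depth limits what 0 counts exclude, to 0.0348 CPM over all libraries. In simulated data without structure shared between libraries, 55.2% of genes above 5 CPM changed 1.5-fold were called. Whether depth or the spread between libraries limits that was not tested.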

Other observations

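The tests of GYY+LPS against control and of the lists of early and later genes were chosen after the data were seen. GYY+LPS against control addressed how far cells with both agents, GYY named first, stood from untreated cells. IFIT2 (5.21 ± 0.15, adjusted p = 6.72e-20), IFIT3 (3.5 ± 0.13, adjusted p = 1.8e-17), IFIT1 (3.24 ± 0.18, adjusted p = 2.25e-13) and CXCL10 (4.89 ± 0.4, adjusted p = 1.12e-09) were above control. ACOD1, which makes itaconate, was higher by 4.7 ± 0.31 (adjusted p = 7.64e-12), TNF by 2.04 ± 0.1 (adjusted p = 1.36e-14) and NFKBIA by 0.91 ± 0.07 (adjusted p = 2.38e-10). CXCL8 (0.44, adjusted p = 0.00175, highest over its alternatives 0.0793) and PTGS2 (0.85 ± 0.18, adjusted p = 0.0186, call lost in 4 of 21 alternatives, highest 0.138) were higher too. HSPA6 was lower (-4.92 ± 0.81, adjusted p = 0.000611, but 0.374 with limma-voom), as were DUSP7, a kinase phosphatase (-0.65 ± 0.12, adjusted p = 0.00237), and LPAR6, a lipid receptor (-0.92 ± 0.18, adjusted p = 0.00479). C5AR2, a complement receptor (-1.22 ± 0.27, adjusted p = 0.0237), and RARA, a retinoic acid receptor (-0.83 ± 0.18, adjusted p = 0.0237), each lost the call in 7 of 21 alternatives (highest 0.178 and 0.208), and IRGQ (-0.71, adjusted p = 0.0196) in 6 (0.148). In all 107 genes were called, 95 higher and 12 lower, 38 and 2 of them by at least 2-fold.

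Of 44 interferon-stimulated genes 12 were above control in GYY+LPS (20 adjusted over the list alone, median 0.34, adjusted p = 0.000428 with an estimated correlation), and of 22 chemokines 9 (12 adjusted over the list alone, adjusted p = 1.98e-05 with an estimated correlation). Of 28 NF-kB genes 9 were higher (17 higher and 2 lower adjusted over the list alone, adjusted p = 0.000457 with an estimated correlation), and of 22 cytokines 3 (6 adjusted over the list alone, adjusted p = 0.0375 with an estimated correlation). Of 31 early primary response genes 16 were higher (22 adjusted over the list alone, adjusted p = 2.57e-08 with an estimated correlation), and of 29 later genes not driven by interferon 4 (11 adjusted over the list alone, adjusted p = 0.0428 with an estimated correlation). In LPS against control these lists had 23 higher and 1 lower of 31 (25 and 1 adjusted over the list alone, adjusted p = 3.46e-06 with an estimated correlation) and 20 higher of 29 (22 adjusted over the list alone, adjusted p = 0.00801 with an estimated correlation).

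HSPA6 varied widely between libraries without GYY, at 12.8, 23.8, 3.77 and 1.34 CPM in control 1 to 4 and 23.8, 9.1, 5.07 and 2.33 in LPS 1 to 4. In the libraries with GYY it was at most 0.555 CPM.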
